A study of Arabidopsis thaliana with 18 samples.

How the data were processed

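Messenger RNA of Arabidopsis thaliana seedlings was sequenced after oligo-dT selection and preparation with a TruSeq kit, per the labels, in 18 libraries of 6 groups with 3 libraries each. Groups were taken from the labels: WT or prmt5 (PRMT5 T-insert) at 22 °C, after 3 days at 37 °C, and 24 h after that heat ended. Recovery temperature, plant age and hour of harvest are not given in the sources used. Reads were assigned to genes of the TAIR10 build with RSEM, per the submitters' processing notes, which give no version. The deposited table holds the authors' TPM (transcript abundance scaled for gene length and to the same total in every library) for 37916 genes. It also holds 6 columns of group means made by the authors, which differed from the mean TPM by at most 3.3e-05, and 0 columns of values stayed unmatched to a sample. TPM keeps no sequencing depth, so depth is unknown, counting intervals were not computed and count models were not used. Gene names and classes came from an annotation of TAIR10.1, matched by gene identifier for 37573 genes, and no coordinates are given. The table holds 157 gene identifiers from transcript assembly.

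All tests used log2(TPM + 1) for the 21831 genes with a mean TPM of at least 1 over the 18 libraries. One model with 6 group means and 12 residual degrees of freedom was fitted with limma 3.58.1 (lmFit, contrasts.fit, and eBayes with trend) in R 4.3.3. The comparisons were heat against 22 °C, recovery against 22 °C and recovery against heat in each genotype, prmt5 against WT in each condition, and 3 interactions, which test the difference between the genotypes' responses. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The level of PRMT5 was tested with an exact permutation of genotype labels within conditions. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables, principal components and plots. Permutations and splits of libraries were run in R.

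Gene groups were 34 lists, 30 of them written member by member with 674 identifiers, of which 0 were missing and 1 (IMA3) was dropped since its identifier carries another gene's name. They cover heat shock factors, small heat shock proteins, other chaperones, co-chaperones, the unfolded protein response, reactive oxygen, arginine methyltransferases, the clock, flowering time, photosynthesis, senescence, abscisic acid, jasmonate, salicylic acid, flavonoids, the cell cycle, DNA damage, SR proteins, Sm and LSm proteins, auxin and elongation, iron, autophagy, ribosome biogenesis and sugar starvation. The others are root, stomatal, vascular, meristem, seed and floral markers, ribosomal proteins, the proteasome, and plastid-encoded and mitochondrion-encoded genes. The ribosomal protein list includes a few mitochondrion-encoded members and pseudogenes. Each list with at least 5 tested members was tested with camera of limma at a preset correlation of 0.01, adjusted over 384 tests, and repeated with an estimated correlation and with fry, which asks only whether a list's genes move in 1 direction and compares them with no other genes.

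Genes were named by a rule: PRMT5, the 5 highest and the 5 lowest log2 changes among genes with a symbol, an adjusted p under 0.05, a mean TPM of at least 5 in the higher group and groups that did not overlap (for an interaction, in at least 1 response), and from each list up to 4 members with the largest change past the threshold. From these the text names a part. Genes of the organelles and ribosomal RNA are described only as classes. Lists, comparisons, the naming rule and most alternatives were set before the data were examined. Those alternatives were pseudocounts of 0.1 and 5, a minimum mean TPM of 5 or none, median-ratio scaling, quantile normalization, organelle genes left out, only the groups compared in the fit, robust eBayes, array weights, a replicate block and leaving out each library. Another 2 alternatives were added later: only nuclear protein-coding genes outside the chromosome 2 copy of mitochondrial DNA, and no genes listed at 0 in 1 library beside at least 10 TPM in the other 2, of which there were 98. TPM of 0 was kept as 0, and log2(TPM + 1) understates changes of low genes.

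Changes were simulated in the prmt5 and WT heat libraries. Of 50 genes each, 0% passed at 1.25-fold, 12% at 1.5, 70% at 2 and 96% at 4. Called were 1 of 21372 unchanged genes, 10 of 10 lists moved by 0.5 (log2) and 1 of 30 left alone. The real data held far more changed genes, so these rates do not carry over.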

Results

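RNA from Arabidopsis thaliana seedlings was sequenced in 18 libraries, 3 for each of 6 groups. Wild-type plants (WT) and plants with an insertion in PRMT5 (prmt5) were kept at 22 °C, or held for 3 days at 37 °C and sampled at once (0 h, called heat) or 24 h later (called recovery). PRMT5 encodes a protein arginine methyltransferase that puts symmetric dimethyl marks on arginines, with Sm and LSm proteins of the splicing machinery and the glycine-rich RNA-binding protein GRP7 among its known substrates. The stated purpose was to find genes whose response to long heat, and to the return from it, depends on PRMT5. The files hold TPM, not read counts, so depth is unknown. The labels do not say that the 3 libraries of a group came from separately grown plants, so every p-value measures only the spread between these libraries, which may be technical. Mean TPM is given with its standard deviation (SD, n = 3 per group) and log2 changes with their standard error. Each of the 5 highest and 5 lowest genes named per comparison of 2 groups had groups that did not overlap, by the naming rule. Chance gives this to 10% of genes with 3 libraries against 3. Among all tested genes it held for 31.3% (genotypes at 22 °C) to 80.3% (prmt5 heat against 22 °C). Gene groups are counted as rose, fell or did not pass at an adjusted p of 0.05 from limma over all genes, and the counts adjusted over the list alone are given wherever they differ. The median given for a list is that of its members' log2 changes. Where median-ratio scaling (MR) or quantile normalization (Q) turned it or moved it by over 1.5 times, that median follows, with the members up and down where their balance moved by over 10 points. With an estimated correlation between members, camera called none of the lists (0 of 384 tests, against 174 with its preset correlation and 267 with fry).

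The insertion lowered the transcript it targets. PRMT5 (AT4G31120) stood at 26.3 ± 1.08 TPM in WT at 22 °C, and at 3.39 ± 1.1 TPM in prmt5. At heat the values were 45.9 ± 1.75 and 6.65 ± 1.93 TPM, and at recovery 39.8 ± 1.08 and 3.79 ± 0.350 TPM. Over all conditions the mean difference, prmt5 minus WT, was -32.74 TPM (exact permutation test within conditions, two-sided p = 0.00025, the smallest that 8000 arrangements can give). Within a condition the differences were -22.93 TPM at 22 °C, -39.25 TPM at heat and -36.04 TPM at recovery, each with an exact two-sided p of 0.1, the smallest that 20 arrangements allow. The transcript rose at heat, by 0.78 ± 0.17 on the log2 scale in WT (adjusted p = 0.00049) and by 0.80 ± 0.17 in prmt5 (adjusted p = 0.00032). At recovery it was still above 22 °C in WT, by 0.58 ± 0.17 (adjusted p = 0.0058, a call that ended under median-ratio scaling), and not past the threshold in prmt5 (log2 change 0.15 ± 0.17, adjusted p = 0.41, negative under quantile normalization).

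**Figure D1:**
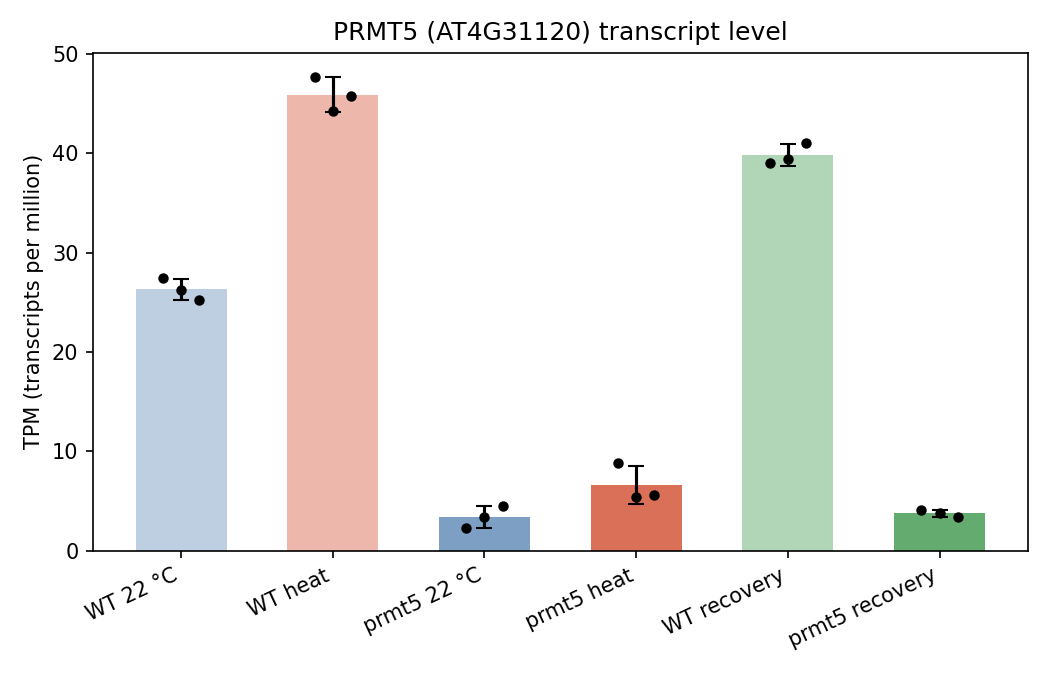
PRMT5 transcript level in TPM by genotype and condition; points are libraries, and bars with error bars are the mean and SD of 3 libraries. The WT groups average 26.3, 45.9 and 39.8 TPM and the prmt5 groups 3.39, 6.65 and 3.79 TPM.

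Condition separated the libraries more than genotype did at 22 °C. The first principal component held 53.3% of the variance, the next 23.1% and the third 10.6%. Correlations between libraries of 1 group, across genes that are not independent replicates, ran from 0.964 to 0.986. Transcripts of nuclear ribosomal RNA genes took 0.39% of TPM in WT at 22 °C and 1.64% at heat, and 0.509% and 2.24% in prmt5. Mitochondrion-encoded genes rose from 0.007% to 2.272% of TPM in WT and from 0.010% to 2.327% in prmt5. Library 3 of prmt5 at recovery stood apart, with 1.312% of TPM in small nucleolar RNA and 0.862% in mitochondrion-encoded genes.

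**Figure D2:**
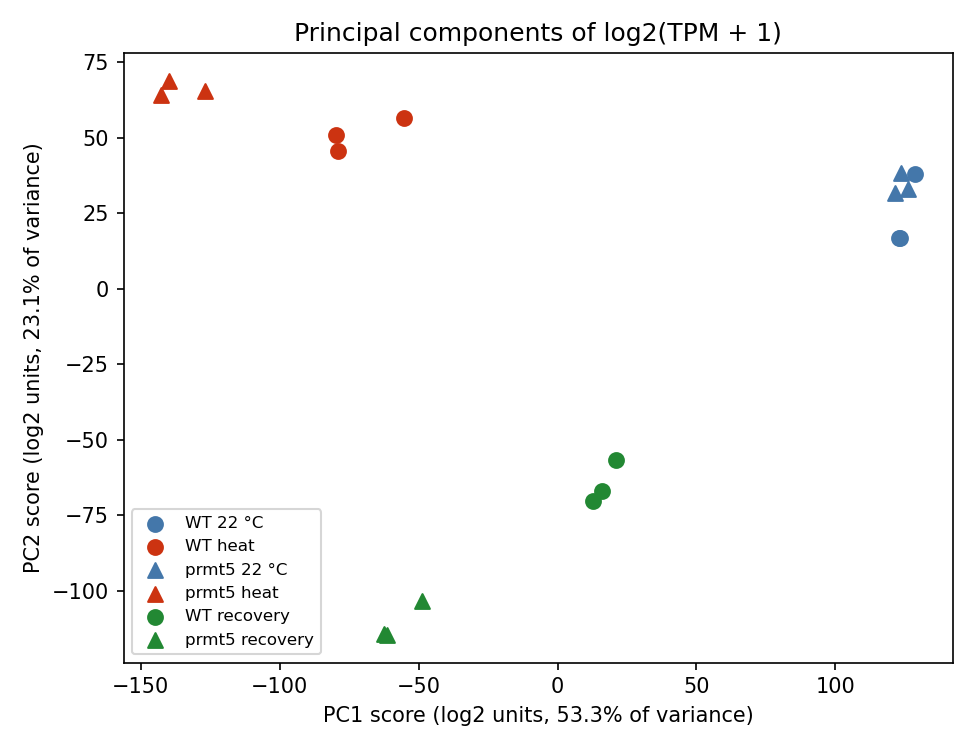
Principal components 1 and 2 of log2(TPM + 1) over the tested genes, with the share of variance on each axis; each point is 1 of 18 libraries, coloured by condition and shaped by genotype. The axes carry 53.3% and 23.1% of the variance.

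Heat for 3 days switched on the heat shock response of WT seedlings. Small heat shock protein, chaperone, co-chaperone, autophagy and proteasome genes rose. Clock genes rose too, by heat or by the hour of harvest. Photosynthesis, flavonoid, iron and ribosomal protein genes and root markers fell. Of the chaperones, HSP17.6II (AT5G12020), a cytosolic small heat shock protein, went from 0.133 ± 0.231 to 1103 ± 281 TPM, a log2 change of 9.91 ± 0.21 (adjusted p = 4.4e-15). HSP17.6C-CI (AT1G53540), another small heat shock protein, reached 833 ± 147 TPM and the plastid protein HSP21 (AT4G27670), listed at 0 at 22 °C, 543 ± 91.5 TPM. 17 of 19 small heat shock protein genes rose, 1 fell and 1 did not pass (median 6.41, camera adjusted p = 2.02e-07, adjusted p = 0.505 with an estimated correlation). HSP70-4 (AT3G12580), an inducible HSP70, rose from 21.4 ± 7.54 to 1387 ± 260 TPM, HSP90.1 (AT5G52640) by 6.25 ± 0.16 and the disaggregase HSP101 (AT1G74310) by 3.83 ± 0.14. 20 of 23 genes for HSP70, HSP90 and HSP100 chaperones rose, 2 fell and 1 did not pass (median 1.26, camera adjusted p = 0.000311, adjusted p = 0.707 with an estimated correlation). Of the co-chaperones and other heat response genes, the immunophilin ROF2 (AT5G48570) rose by 6.97 ± 0.16, the galactinol synthase GOLS1 (AT2G47180) by 6.5 ± 0.18 and the HSP70-HSP90 organizer HOP3 (AT4G12400) by 5.32 ± 0.17. 17 of 18 genes of that list rose, 0 fell and 1 did not pass (median 3.19, camera adjusted p = 1.55e-06, adjusted p = 0.529 with an estimated correlation). The heat shock factors that carry acquired thermotolerance, HSFA2 (AT2G26150) and HSFA3 (AT5G03720), rose by 4.54 ± 0.21 and 4.55 ± 0.14. 13 of 18 factors rose, 2 fell and 3 did not pass (median 1.2, camera adjusted p = 0.0687). APX2 (AT3G09640), the cytosolic ascorbate peroxidase driven by heat shock factors, rose from 0.0367 ± 0.0351 to 163 ± 23.8 TPM while MDAR3 (AT3G09940) fell by 2.82. 15 of 31 genes for the scavenging of reactive oxygen rose, 11 fell and 5 did not pass (median 0.27, MR -0.13 with 9 up and 14 down, camera adjusted p = 0.626), with a test direction opposite to the median.

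On the TPM scale quality control lists rose too. NAC103 (AT5G64060), a transcription factor of the unfolded protein response, rose from 0.337 ± 0.296 to 27.1 ± 4.18 TPM, and its upstream sensors BZIP28 (AT3G10800) and IRE1A (AT2G17520) rose by 2.16 ± 0.09 and 1.94 ± 0.10. 20 of 24 unfolded protein response genes rose, 1 fell and 3 did not pass (median 0.52, MR 0.16 with 10 up and 3 down, camera adjusted p = 0.00825, adjusted p = 0.747 with an estimated correlation). The ubiquitin-like proteins ATG8B (AT4G04620) and ATG8D (AT2G05630), which build autophagosomes, rose by 2.65 ± 0.16 and 2.14 ± 0.10. 19 of 21 autophagy genes rose, 1 fell and 1 did not pass (median 1.08, MR 0.70, camera adjusted p = 0.000785, adjusted p = 0.653 with an estimated correlation). The proteasome subunit genes RPT1B (AT1G53780) and RPN2B (AT1G04810) rose by 2.04 ± 0.34 and 1.59 ± 0.11. 38 of 52 proteasome genes rose, 2 fell and 12 did not pass (median 0.56, MR 0.15 with 23 up and 13 down, camera adjusted p = 0.00384, adjusted p = 0.8 with an estimated correlation). Under MR the unfolded protein response and the proteasome were no longer called. The splicing factor gene SR30 (AT1G09140) rose by 3.58 ± 0.11. 11 of 20 SR protein genes rose, 3 fell and 6 did not pass (median 0.82, MR 0.42 with 11 up and 7 down, camera adjusted p = 0.188). SMD2B (AT3G62840), a core spliceosomal Sm protein, went from 219 ± 14.3 to 1856 ± 93.9 TPM. 17 of 27 genes for Sm and LSm proteins and other PRMT5 substrates rose, 6 fell and 4 did not pass (18 up and 6 down adjusted over the list alone, median 0.37, MR -0.029 with 11 up and 9 down, Q 0.17, camera adjusted p = 0.273). PRMT3 (AT3G12270), needed for ribosome assembly, rose from 20 ± 0.868 to 49.2 ± 4.71 TPM and PRMT4A (AT5G49020) fell by 1.05. 6 of 9 protein arginine methyltransferase genes rose, 2 fell and 1 did not pass (median 0.38, MR -0.018 with 3 up and 2 down, Q 0.094, camera adjusted p = 0.82).

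Photosynthesis genes went the other way. RBCS1A (AT1G67090), a small subunit of Rubisco, dropped from 18970 ± 1160 to 1429 ± 473 TPM, and the antenna genes LHCB1.4 (AT2G34430) and LHCB2.3 (AT3G27690) fell by 3.81 and 3.76 on the log2 scale. 45 of 55 nuclear photosynthesis genes fell, 1 rose and 9 did not pass (median -1.82, camera adjusted p = 1.42e-11, adjusted p = 0.722 with an estimated correlation). Flavonol synthase FLS1 (AT5G08640) went from 125 ± 21 to 6.07 ± 0.845 TPM and the anthocyanin regulator PAP2 (AT1G66390) fell by 2.66. 16 of 20 flavonoid genes fell, 1 rose and 3 did not pass (median -1.43, camera adjusted p = 2.78e-06, adjusted p = 0.653 with an estimated correlation). The iron-deficiency peptides IMA1 (AT1G47400) and IMA2 (AT1G47395) fell by 4.45 and 4.33 and the root iron transporter IRT1 (AT4G19690) by 3.45. 15 of 22 iron genes fell, 3 rose and 4 did not pass (median -1.75, camera adjusted p = 2.58e-05, adjusted p = 0.505 with an estimated correlation). The root hair peroxidase PRX73 (AT5G67400) dropped by 3.27. 15 of 23 root markers fell, 2 rose and 6 did not pass (median -1.22, camera adjusted p = 0.00117, adjusted p = 0.747 with an estimated correlation). Ribosomal protein genes moved less. 151 of 247 members fell, 63 rose and 33 did not pass (64 up and 151 down adjusted over the list alone, median -0.45, MR -0.85 with 35 up and 174 down, Q -0.26, camera adjusted p = 2.44e-09, adjusted p = 0.747 with an estimated correlation). The mitotic cyclin CYCB1;4 (AT2G26760) fell by 2.00 and the replication helicase gene MCM4 (AT2G16440) rose by 1.79 ± 0.15. 18 of 34 cell cycle genes fell, 13 rose and 3 did not pass (median -0.56, MR -0.93, Q -0.97, camera adjusted p = 0.0787). The DNA damage factors NAC044 (AT3G01600) and NAC085 (AT5G14490), which arrest the cycle at its second gap, rose by 5.66 ± 0.19 and 5.01 ± 0.13. 12 of 24 genes of their list rose, 3 fell and 9 did not pass (median 0.55, MR 0.19 with 12 up and 9 down, Q 0.14 with 11 up and 8 down, camera adjusted p = 0.291). The clock genes PRR7 (AT5G02810), LNK1 (AT5G64170) and GI (AT1G22770) rose by 4.54 ± 0.13, 4.1 ± 0.13 and 3.81 ± 0.16. 20 of 25 clock genes rose, 2 fell and 3 did not pass (median 0.63, MR 0.26 with 14 up and 4 down, Q 0.27, camera adjusted p = 0.00794, adjusted p = 0.653 with an estimated correlation).

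Tissue markers moved in several directions. The growth regulator PIF4 (AT2G43010), which drives elongation in warmth, rose by 2.93 ± 0.23 and the expansin EXPA11 (AT1G20190) fell by 2.42. 15 of 27 elongation genes rose, 6 fell and 6 did not pass (median 0.63, MR 0.26 with 10 up and 7 down, Q 0.22 with 7 up and 7 down, camera adjusted p = 0.954), the test direction being opposite to the median. The stomatal genes TMM (AT1G80080) and SPCH (AT5G53210) fell by 1.60 and 1.55. 5 of 10 stomatal lineage markers fell, 1 rose and 4 did not pass (1 up and 4 down adjusted over the list alone, median -0.40, MR -0.73 with 0 up and 7 down, Q -0.74 with 0 up and 7 down, camera adjusted p = 0.0721). The xylem protease XCP2 (AT1G20850) rose by 2.08 ± 0.14 and the phloem sucrose transporter SUC2 (AT1G22710) fell by 1.82. 6 of 11 vascular markers rose, 3 fell and 2 did not pass (median 0.57, MR 0.18 with 5 up and 4 down, Q 0.21 with 5 up and 4 down, camera adjusted p = 0.981), again with a test direction opposite to the median. 1 of 2 seed maturation genes rose, 0 fell and 1 did not pass (1 up and 1 down adjusted over the list alone, too few members for camera), and the storage protein gene SESA1 (AT4G27140) was listed at 0 at 22 °C and at 19.5 ± 16.8 TPM at heat. 26 of 27 mitochondrion-encoded genes rose, 0 fell and 1 did not pass (median 7.22, camera adjusted p = 1.42e-11, adjusted p = 0.505 with an estimated correlation). In the same libraries 14 of 54 plastid-encoded genes fell, 10 rose and 30 did not pass (3 up and 13 down adjusted over the list alone, median 0.018, MR -0.34 with 3 up and 18 down, Q -0.36 with 3 up and 19 down, camera adjusted p = 0.0409, adjusted p = 0.757 with an estimated correlation), with a mean and test that pointed down. Their share of TPM was 0.078% at 22 °C and 0.197% at heat, where library 2 stood apart at 0.423%. ATP9 (AT2G07671), which went from 2.82 ± 0.669 to 7549 ± 504 TPM, lies in the copy of mitochondrial DNA on chromosome 2 and shares reads with the organelle.

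In all, 16481 of 21831 tested genes changed in WT at heat, 10879 higher and 5602 lower, and 5659 and 2961 of them by more than 2-fold. Under median-ratio scaling, which moved the median change of all genes from 0.35 to 0, the split was 8075 higher and 8177 lower, and for small changes the direction rests on the TPM scale.

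In prmt5 many of the WT programs moved, some further, some less. Small heat shock proteins, chaperones and co-chaperones rose, the unfolded protein response and autophagy rose, and photosynthesis and flavonoid genes fell steeply. HSP17.6II reached 1050 ± 220 TPM. 18 of 19 small heat shock protein genes rose, 1 fell and 0 did not pass (median 6.65, camera adjusted p = 1.25e-06, adjusted p = 0.505 with an estimated correlation). HSP90.1 rose by 6.88 ± 0.16 (adjusted p = 1.2e-14) and HSP70-4 to 1564 ± 51.1 TPM. 20 of 23 chaperone genes rose, 0 fell and 3 did not pass (median 1.68, camera adjusted p = 1.81e-05, adjusted p = 0.659 with an estimated correlation). The thermotolerance J-protein gene TMS1 (AT3G08970) rose by 6.36 ± 0.13 and HOP3 by 6.32 ± 0.17. 18 of 18 co-chaperone and other heat response genes rose, 0 fell and 0 did not pass (median 3.69, camera adjusted p = 2.57e-07, adjusted p = 0.505 with an estimated correlation). The disulfide isomerases PDIL2-3 (AT2G32920) and PDIL2-2 (AT1G04980), which fold proteins in the endoplasmic reticulum, rose by 3.42 ± 0.08 and 3.42 ± 0.09. 23 of 24 unfolded protein response genes rose, 1 fell and 0 did not pass (median 1.71, camera adjusted p = 8.58e-07, adjusted p = 0.579 with an estimated correlation). ATG8A (AT4G21980) went from 44.2 ± 3.62 to 422 ± 46.8 TPM and ATG8H (AT3G06420) rose by 2.91 ± 0.21. 21 of 21 autophagy genes rose, 0 fell and 0 did not pass (median 2.01, camera adjusted p = 7.29e-07, adjusted p = 0.505 with an estimated correlation). RPT3 (AT5G58290), an ATPase of the proteasome base, went from 116 ± 10.1 to 741 ± 59.1 TPM. 42 of 52 proteasome genes rose, 4 fell and 6 did not pass (median 0.89, camera adjusted p = 1.22e-05, adjusted p = 0.747 with an estimated correlation). The Sm genes SMD3A (AT1G76300) and SMB-A (AT5G44500) rose by 2.47 ± 0.08 and 2.17 ± 0.12 while GRP7 (AT2G21660) fell by 2.13. 20 of 27 genes of the list rose, 7 fell and 0 did not pass (median 1.16, camera adjusted p = 0.0165, adjusted p = 0.747 with an estimated correlation).

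The Rubisco gene RBCS1B (AT5G38430) dropped from 8142 ± 1360 to 70.9 ± 36.3 TPM, and the photosystem genes PSBTN (AT3G21055) and PSAD1 (AT4G02770) fell by 6.52 and 6.45. 54 of 55 photosynthesis genes fell, 0 rose and 1 did not pass (median -3.7, camera adjusted p = 9.98e-14, adjusted p = 0.707 with an estimated correlation). The anthocyanin enzymes LDOX (AT4G22880) and DFR (AT5G42800) fell by 5.84 and 5.82. 19 of 20 flavonoid genes fell, 0 rose and 1 did not pass (median -2.41, camera adjusted p = 9.18e-07, adjusted p = 0.626 with an estimated correlation). The nicotianamine synthases NAS1 (AT5G04950) and NAS4 (AT1G56430), which make a metal chelator, fell by 5.91 and 5.55. 19 of 22 iron genes fell, 3 rose and 0 did not pass (median -2.11, camera adjusted p = 0.000117, adjusted p = 0.505 with an estimated correlation). TSO2 (AT3G27060), a ribonucleotide reductase of the S phase, fell by 4.24. KN (AT1G08560), the syntaxin of the dividing cell plate, fell by 3.75. 23 of 34 cell cycle genes fell, 6 rose and 5 did not pass (median -1.1, camera adjusted p = 0.000406, adjusted p = 0.747 with an estimated correlation). The meristem genes KNAT1 (AT4G08150) and STM (AT1G62360) fell by 2.42 and 1.47. 6 of 6 meristem and boundary markers fell, 0 rose and 0 did not pass (median -1.43, camera adjusted p = 0.0247, adjusted p = 0.707 with an estimated correlation). 144 of 247 ribosomal protein genes fell, 64 rose and 39 did not pass (median -0.38, camera adjusted p = 0.000332, adjusted p = 0.831 with an estimated correlation). 26 of 27 mitochondrion-encoded genes rose, 0 fell and 1 did not pass (median 6.86, camera adjusted p = 3.58e-10, adjusted p = 0.505 with an estimated correlation). 31 of 54 plastid-encoded genes fell, 0 rose and 23 did not pass (0 up and 28 down adjusted over the list alone, median -0.88, camera adjusted p = 0.000406, adjusted p = 0.707 with an estimated correlation). In all 17783 genes changed, 9930 higher and 7853 lower, and 6055 and 5155 of them by more than 2-fold.

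The heat responses of WT and prmt5 shared 8607 higher genes, against 4948.4 expected if the lists were independent, and 5015 lower genes against 2015.1. Another 847 genes changed in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.845 and rho = 0.833. Of the 13622 shared genes, 9124 (67%) changed more in prmt5, with median sizes of 1.14 in WT and 1.48 in prmt5.

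At 22 °C the genotypes differed little beside the heat responses. In prmt5 some cold and dehydration, iron-deficiency and Sm protein genes and GRP7 were higher, and some flowering-time genes, antioxidant enzymes and a jasmonate-induced defensin were lower. The cold-induced genes COR15A (AT2G42540) and KIN2 (AT5G15970) stood at 156 ± 122 and 737 ± 229 TPM in prmt5, against 19 ± 14.4 and 109.7 ± 30.1 TPM in WT, with log2 differences of 2.98 ± 0.50 and 2.73 ± 0.26 (adjusted p = 0.0013 and 1.3e-05). 5 of 28 abscisic acid, dehydration and cold genes rose, 3 fell and 20 did not pass (median 0.18, camera adjusted p = 0.00705, adjusted p = 0.707 with an estimated correlation). The defensin PDF1.2A (AT5G44420) stood at 1.65 ± 0.811 TPM against 26 ± 12 in WT, and CIB1 (AT4G34530), a cryptochrome partner that promotes flowering, was at -2.45. The florigen gene FT (AT1G65480) and the floral activator AGL24 (AT4G24540) were lower, at -1.79 and -1.69. 7 of 21 flowering time genes fell, 0 rose and 14 did not pass (0 up and 10 down adjusted over the list alone, median -0.23, MR -0.13, Q -0.048, camera adjusted p = 0.0238, adjusted p = 0.742 with an estimated correlation). The clock gene PRR7 was higher by 1.76 ± 0.13 and the morning genes RVE8 (AT3G09600) and LHY (AT1G01060) were at -2.07 and -1.66. 8 of 25 clock genes rose, 6 fell and 11 did not pass (8 up and 8 down adjusted over the list alone, median -0.020, MR 0.12, Q 0.18, camera adjusted p = 0.308), with a test direction opposite to the median. Catalase CAT2 (AT4G35090) and the copper superoxide dismutases CSD1 (AT1G08830) and CSD2 (AT2G28190) were at -1.7, -1.2 and -1.15. 6 of 31 scavenging genes fell, 1 rose and 24 did not pass (median -0.14, MR 0.010 with 2 up and 6 down, camera adjusted p = 0.174).

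Among genes of the methylation targets, GRP7 stood at 6484 ± 833 TPM in prmt5 against 2801 ± 184 in WT and SMD1A (AT3G07590) was higher by 0.66 ± 0.08. 6 of 27 members of that list rose, 0 fell and 21 did not pass (median 0.19, MR 0.34, camera adjusted p = 4.05e-10, adjusted p = 0.505 with an estimated correlation), 14 up under MR. 1 of 9 methyltransferase genes rose, 2 fell and 6 did not pass (1 up and 3 down adjusted over the list alone, median -0.12, MR 0.023 with 3 up and 2 down, Q -0.018 with 3 up and 2 down, camera adjusted p = 0.625), with PRMT5 at -2.67 ± 0.17 and PRMT1B (AT4G29510) at 0.33 ± 0.09. The iron-deficiency regulators BHLH100 (AT2G41240) and BHLH101 (AT5G04150) were higher by 1.72 ± 0.34 and 1.59 ± 0.31. 7 of 22 iron genes rose, 0 fell and 15 did not pass (9 up and 1 down adjusted over the list alone, median 0.28, MR 0.43, camera adjusted p = 3.16e-05, adjusted p = 0.505 with an estimated correlation). NAC103 was higher by 2.15 ± 0.18. 3 of 24 unfolded protein response genes rose, 0 fell and 21 did not pass (median 0.024, MR 0.17, Q 0.087, camera adjusted p = 0.00593, adjusted p = 0.747 with an estimated correlation), 7 up under MR. NAC044 was higher by 1.93 ± 0.19. 4 of 24 DNA damage genes rose, 1 fell and 19 did not pass (5 up and 1 down adjusted over the list alone, median 0.025, MR 0.16, Q 0.14, camera adjusted p = 0.0199, adjusted p = 0.747 with an estimated correlation). The cell plate gene KN was higher by 0.68 ± 0.14. 4 of 34 cell cycle genes rose, 0 fell and 30 did not pass (3 up and 0 down adjusted over the list alone, median 0.096, MR 0.24, Q 0.22, camera adjusted p = 0.000311, adjusted p = 0.747 with an estimated correlation), 9 up under MR. The antenna gene LHCB1.2 (AT1G29910) was higher by 1.89 ± 0.37. 5 of 55 photosynthesis genes rose, 2 fell and 48 did not pass (median 0.42, Q 0.20 with 5 up and 1 down, camera adjusted p = 4.85e-07, adjusted p = 0.747 with an estimated correlation). HSP15.4 (AT4G21870) was at -1.34. 4 of 19 small heat shock protein genes fell, 2 rose and 13 did not pass (3 up and 4 down adjusted over the list alone, median 0.18, MR 0.32 with 3 up and 3 down, Q 0.35 with 3 up and 2 down, camera adjusted p = 0.0427, adjusted p = 0.747 with an estimated correlation).

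In all 3256 genes differed at 22 °C, 795 higher and 2461 lower in prmt5, and 128 and 284 by more than 2-fold. Under median-ratio scaling, which moved the median of all genes from -0.10 to 0.007, the split was 2015 higher and 1632 lower. Only the groups compared in the fit gave 1498 genes, leaving out WT library 1, WT library 2 or prmt5 library 2 gave 1679, 1989 and 1762, and array weights, whose fit stopped before convergence, gave 13082. The small heat shock protein, cold, flowering time and DNA damage calls ended under several alternatives, among them array weights or the fit of only these groups, and BHLH100 and PRMT1B no longer passed under at least 1 alternative.

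At the end of heat the genotypes stood far apart. Genes for folding in the endoplasmic reticulum, autophagy, the proteasome and Sm proteins were higher in prmt5, and photosynthesis, jasmonate, flavonoid, cell cycle and meristem genes were lower. The calnexin CNX1 (AT5G61790) and the lumenal HSP70 BIP2 (AT5G42020) stood at 1207 ± 91 and 1025 ± 87.8 TPM in prmt5, against 294 ± 22.2 and 252 ± 26 TPM in WT, and PDIL2-2 was higher by 2.42 ± 0.09 (adjusted p = 5.7e-11). 22 of 24 unfolded protein response genes rose, 1 fell and 1 did not pass (median 0.96, camera adjusted p = 3.12e-13, adjusted p = 0.505 with an estimated correlation). HSP70-17 (AT4G16660), of the same compartment, was higher by 1.75 ± 0.12 and the plastid HSP90.5 (AT2G04030) was at -1.06. 13 of 23 chaperone genes rose, 2 fell and 8 did not pass (median 0.39, MR 0.78, camera adjusted p = 5.61e-05, adjusted p = 0.7 with an estimated correlation). TMS1 was higher by 1.97 ± 0.13. 10 of 18 co-chaperone genes rose, 2 fell and 6 did not pass (median 0.42, MR 0.82, camera adjusted p = 0.000111, adjusted p = 0.659 with an estimated correlation). Small heat shock proteins were split, HSP15.4 and HSP14.7 (AT5G47600) being at -2.26 and -1.79. 4 of 19 members rose, 7 fell and 8 did not pass (median 0.053, MR 0.45 with 9 up and 5 down, Q -0.15, camera adjusted p = 0.651), with a negative mean. ATG8H and ATG8E (AT2G45170) were higher by 1.97 ± 0.21 and 1.5 ± 0.12. 17 of 21 autophagy genes rose, 1 fell and 3 did not pass (median 0.80, camera adjusted p = 1.56e-09, adjusted p = 0.505 with an estimated correlation). RPT3 was higher by 1.57 ± 0.10 and the core subunit PAD1 (AT3G51260) by 1.26 ± 0.06. 36 of 52 proteasome genes rose, 8 fell and 8 did not pass (median 0.40, MR 0.79 with 43 up and 3 down, camera adjusted p = 8.77e-11, adjusted p = 0.653 with an estimated correlation). The Sm and LSm genes SME1 (AT2G18740) and LSM6B (AT2G43810) were higher by 1.45 ± 0.09 and 1.46 ± 0.09. 18 of 27 genes of their list rose, 4 fell and 5 did not pass (median 0.53, MR 0.92 with 22 up and 1 down, camera adjusted p = 7.96e-08, adjusted p = 0.505 with an estimated correlation). ERF114 (AT5G61890), an ethylene-response factor of bud growth, stood at 116 ± 31.2 TPM against 6.58 ± 2.14 in WT, and the pectin enzyme gene GAUT14 (AT5G15470) at 21.2 ± 2.0 TPM against 0 in WT.

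The jasmonate-induced storage protein VSP2 (AT5G24770) stood at 2.33 ± 2.23 TPM against 83.8 ± 37.6 in WT, and the lipoxygenase LOX2 (AT3G45140), which starts jasmonate synthesis, at 18.6 ± 12.5 against 342 ± 66.8 TPM. 20 of 30 jasmonate genes fell, 2 rose and 8 did not pass (median -0.96, Q -0.64, camera adjusted p = 0.0283, adjusted p = 0.747 with an estimated correlation), a call that ended without WT heat library 2 (median -0.78). IPMI1 (AT3G58990), an enzyme of glucosinolate chain elongation, was at -4.52. The antenna genes LHCB6 (AT1G15820) and LHCB3 (AT5G54270) were at -3.44 and -3.29. 48 of 55 photosynthesis genes fell, 0 rose and 7 did not pass (median -1.72, camera adjusted p = 0.000182, adjusted p = 0.824 with an estimated correlation). LDOX and the anthocyanin regulator PAP1 (AT1G56650) were at -3.75 and -3.0. 19 of 20 flavonoid genes fell, 0 rose and 1 did not pass (median -1.4, Q -0.87, camera adjusted p = 0.00221, adjusted p = 0.747 with an estimated correlation). TSO2 stood at 8.55 ± 2.7 TPM against 57.9 ± 5.59 in WT. 26 of 34 cell cycle genes fell, 2 rose and 6 did not pass (2 up and 27 down adjusted over the list alone, median -1.07, Q -0.65, camera adjusted p = 0.000735, adjusted p = 0.747 with an estimated correlation). KNAT1 and STM, which keep meristem cells undifferentiated, were at -2.56 and -2.04. 6 of 6 meristem and boundary markers fell, 0 rose and 0 did not pass (median -1.12, Q -0.61, camera adjusted p = 0.073). In all 14885 genes differed, 4344 higher and 10541 lower in prmt5, and 1208 and 4882 by more than 2-fold. Under median-ratio scaling, which moved the median of all genes from -0.34 to -0.010, the split was 7351 higher and 7258 lower. Under quantile normalization the chaperone and co-chaperone calls ended, with medians of 0.28 and 0.35.

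After 24 h of recovery ribosome biogenesis genes of WT seedlings stood above 22 °C, and so did ribosomal protein genes on the TPM scale. Senescence, defence, DNA damage and autophagy genes stood higher than at 22 °C, and photosynthesis and iron genes lower. The senescence marker SAG13 (AT2G29350) stood at 299 ± 31.4 TPM against 0.777 ± 0.499 at 22 °C, a log2 change of 7.43 ± 0.42 (adjusted p = 1.1e-09). The starvation ribonuclease RNS1 (AT2G02990) rose by 6.05 ± 0.26. The stress factor NAC019 (AT1G52890) rose by 4.13 ± 0.21. 16 of 20 senescence genes rose, 2 fell and 2 did not pass (median 1.67, camera adjusted p = 0.00383, adjusted p = 0.626 with an estimated correlation). PAD3 (AT3G26830), which makes the phytoalexin camalexin, and the immune marker FRK1 (AT2G19190) rose by 3.77 ± 0.38 and 3.08 ± 0.38. 18 of 22 salicylic acid and defence genes rose, 2 fell and 2 did not pass (median 1.99, camera adjusted p = 0.00592, adjusted p = 0.707 with an estimated correlation). The cyclin-dependent kinase inhibitors SMR5 (AT1G07500), listed at 0 at 22 °C, and SMR7 (AT3G27630) reached 44.9 ± 16.6 and 51.4 ± 6.58 TPM. 17 of 24 DNA damage genes rose, 0 fell and 7 did not pass (18 up and 0 down adjusted over the list alone, median 1.02, MR 0.67 with 14 up and 3 down, camera adjusted p = 0.00147, adjusted p = 0.707 with an estimated correlation). The nucleolar genes SWA1 (AT2G47990) and TOZ (AT5G16750) rose by 1.33 ± 0.16 and 1.3 ± 0.13. 19 of 19 ribosome biogenesis genes rose, 0 fell and 0 did not pass (median 1.1, MR 0.72, camera adjusted p = 0.000208, adjusted p = 0.747 with an estimated correlation). RPS23A (AT3G09680) rose by 3.51 ± 0.18. 203 of 247 ribosomal protein genes rose, 2 fell and 42 did not pass (205 up and 2 down adjusted over the list alone, median 0.46, MR 0.067 with 64 up and 29 down, camera adjusted p = 1.93e-06, adjusted p = 0.763 with an estimated correlation). HSP18.2 (AT5G59720) was still up by 5.76 ± 0.34. 13 of 19 small heat shock protein genes rose, 2 fell and 4 did not pass (14 up and 3 down adjusted over the list alone, median 2.58, camera adjusted p = 0.0409, adjusted p = 0.747 with an estimated correlation). The constitutive chaperones HSC70-1 (AT5G02500) and HSC70-3 (AT3G09440) were at -1.84 and -2.16. 11 of 23 chaperone genes rose, 8 fell and 4 did not pass (median 0.31, MR -0.061 with 7 up and 10 down, Q -0.011, camera adjusted p = 0.206), the test pointing down. The autophagy receptor NBR1 (AT4G24690) rose by 1.84 ± 0.09. 16 of 21 autophagy genes rose, 1 fell and 4 did not pass (median 0.61, MR 0.23 with 10 up and 3 down, Q 0.29, camera adjusted p = 0.0377, adjusted p = 0.747 with an estimated correlation). RPT5B (AT1G09100) rose by 0.82 ± 0.10. 37 of 52 proteasome genes rose, 0 fell and 15 did not pass (median 0.38, MR -0.0042 with 11 up and 12 down, Q 0.18 with 26 up and 5 down, camera adjusted p = 0.0203, adjusted p = 0.854 with an estimated correlation).

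The Rubisco gene RBCS2B (AT5G38420) stood at 1328 ± 396 TPM against 12250 ± 637, and the antenna gene LHCB4.3 (AT2G40100) fell by 3.85. 49 of 55 photosynthesis genes fell, 0 rose and 6 did not pass (median -1.99, camera adjusted p = 2.89e-22, adjusted p = 0.653 with an estimated correlation). IMA1 fell by 3.67 and the iron store ferritin FER2 (AT3G11050) rose by 3.39 ± 0.17. 13 of 22 iron genes fell, 3 rose and 6 did not pass (median -0.67, camera adjusted p = 7.91e-05, adjusted p = 0.505 with an estimated correlation). The nitrate transporter NRT2.1 (AT1G08090) rose by 3.19 ± 0.14. 5 of 23 root markers rose, 0 fell and 18 did not pass (2 up and 0 down adjusted over the list alone, median 0.085, MR -0.22 with 2 up and 2 down, Q -0.34 with 2 up and 7 down, camera adjusted p = 0.529), the test pointing down. The floral genes AP3 (AT3G54340) and SEP3 (AT1G24260) rose by 2.37 ± 0.18 and 2.21 ± 0.26. 2 of 2 floral markers rose, 0 fell and 0 did not pass (too few members for camera). 23 of 27 mitochondrion-encoded genes rose, 0 fell and 4 did not pass (median 3.27, camera adjusted p = 7.96e-08, adjusted p = 0.505 with an estimated correlation). In all 14646 genes changed, 10871 higher and 3775 lower, and 3881 and 1619 by more than 2-fold. Under median-ratio scaling, which moved the median of all genes from 0.35 to 0.012, the split was 6644 and 6666 and the autophagy, ribosomal protein and proteasome calls ended. The autophagy call also ended without WT recovery library 3 and the small heat shock protein call without WT 22 °C library 3.

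In prmt5 the same comparison showed senescence and defence genes higher and ribosomal protein genes lower than at 22 °C. SAG13 stood at 2042 ± 258 TPM against 0.453 ± 0.271, a log2 change of 10.47 ± 0.42 (adjusted p = 7.2e-12), and RNS1 and the blue copper protein BCB (AT5G20230) reached 1258 ± 41.4 and 1152 ± 325 TPM. 16 of 20 senescence genes rose, 1 fell and 3 did not pass (median 3.03, camera adjusted p = 0.00103, adjusted p = 0.505 with an estimated correlation). PAD3 reached 879 ± 178 TPM and WRKY33 (AT2G38470), which drives it, rose by 5.09 ± 0.27. 17 of 22 salicylic acid and defence genes rose, 3 fell and 2 did not pass (median 1.88, camera adjusted p = 0.0189, adjusted p = 0.742 with an estimated correlation). HSP17.6II was still up by 5.81 ± 0.21. 16 of 19 small heat shock protein genes rose, 1 fell and 2 did not pass (median 2.4, camera adjusted p = 0.00211, adjusted p = 0.707 with an estimated correlation). GOLS1 was still up by 4.4 ± 0.18. 14 of 18 co-chaperone genes rose, 1 fell and 3 did not pass (median 1.51, camera adjusted p = 0.0219, adjusted p = 0.747 with an estimated correlation). ATG8A stood at 259.9 ± 15 TPM. 21 of 21 autophagy genes rose, 0 fell and 0 did not pass (median 1.32, camera adjusted p = 3.6e-05, adjusted p = 0.505 with an estimated correlation). RPT6B (AT5G20000) rose by 1.41 ± 0.09. 46 of 52 proteasome genes rose, 1 fell and 5 did not pass (median 0.55, MR 0.10 with 24 up and 5 down, Q 0.28, camera adjusted p = 0.000406, adjusted p = 0.749 with an estimated correlation), a call that ended under MR. Carbonic anhydrase CA1 (AT3G01500) stood at 7.87 ± 2.11 TPM against 1610 ± 194, and RBCS2B fell by 6.8. 53 of 55 photosynthesis genes fell, 0 rose and 2 did not pass (0 up and 54 down adjusted over the list alone, median -4.23, camera adjusted p = 1.08e-23, adjusted p = 0.626 with an estimated correlation). The anaphase activator CDC20.1 (AT4G33270) fell by 2.79. 18 of 34 cell cycle genes fell, 8 rose and 8 did not pass (median -0.87, Q -1.35 with 2 up and 24 down, camera adjusted p = 5.02e-05, adjusted p = 0.747 with an estimated correlation). FLS1 fell by 2.55. 14 of 20 flavonoid genes fell, 2 rose and 4 did not pass (median -0.88, MR -1.32, camera adjusted p = 0.000994, adjusted p = 0.722 with an estimated correlation). NAS4 fell by 4.76. 15 of 22 iron genes fell, 2 rose and 5 did not pass (median -1.37, camera adjusted p = 8.12e-05, adjusted p = 0.505 with an estimated correlation). The fibrillarin FIB2 (AT4G25630), which methylates ribosomal RNA, fell by 0.68. 4 of 19 ribosome biogenesis genes rose, 4 fell and 11 did not pass (median 0.10, MR -0.34 with 0 up and 11 down, Q -0.27 with 0 up and 11 down, camera adjusted p = 0.33), the test pointing down. 188 of 247 ribosomal protein genes fell, 31 rose and 28 did not pass (33 up and 188 down adjusted over the list alone, median -0.52, MR -0.98, camera adjusted p = 1.24e-16, adjusted p = 0.707 with an estimated correlation). 24 of 27 mitochondrion-encoded genes rose, 0 fell and 3 did not pass (median 4.07, camera adjusted p = 1.06e-06, adjusted p = 0.505 with an estimated correlation). In all 17033 genes changed, 11649 higher and 5384 lower, and 6413 and 3104 by more than 2-fold. Under median-ratio scaling, which moved the median of all genes from 0.45 to 0.061, the split was 8680 and 7854. The genotypes shared 9114 higher genes (5800.8 expected for independent lists) and 3239 lower genes (931 expected), with 575 in opposite directions. Across genes, which are not independent replicates, r was 0.802 and rho 0.782. Of these 12353 shared genes 9780 (79.2%) changed more in prmt5, with median sizes of 0.87 in WT and 1.3 in prmt5.

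Between the end of heat and recovery, chaperone genes of WT seedlings fell and flavonoid, root and ribosomal protein genes rose. HSP17.6II fell by 6.23 to 13.5 ± 2.69 TPM and the mitochondrial HSP23.6 (AT4G25200) by 6.12 (adjusted p = 2.1e-16). 16 of 19 small heat shock protein genes fell, 0 rose and 3 did not pass (1 up and 16 down adjusted over the list alone, median -4.22, camera adjusted p = 3.22e-10, adjusted p = 0.505 with an estimated correlation). HSP70-4 fell by 5.69. 20 of 23 chaperone genes fell, 0 rose and 3 did not pass (median -1.36, camera adjusted p = 7.62e-09, adjusted p = 0.505 with an estimated correlation). LNK1 fell by 2.39 (hour of harvest unknown). 19 of 25 clock genes fell, 2 rose and 4 did not pass (median -0.58, camera adjusted p = 0.000403, adjusted p = 0.505 with an estimated correlation). SR30 fell by 2.6. 14 of 20 SR protein genes fell, 3 rose and 3 did not pass (4 up and 14 down adjusted over the list alone, median -0.68, camera adjusted p = 0.0068, adjusted p = 0.763 with an estimated correlation). DFR rose from 10.7 ± 3.0 to 132 ± 34.6 TPM. 17 of 20 flavonoid genes rose, 0 fell and 3 did not pass (median 2.04, camera adjusted p = 3.26e-06, adjusted p = 0.653 with an estimated correlation). PRX73 rose by 3.17 ± 0.48. 16 of 23 root markers rose, 1 fell and 6 did not pass (16 up and 2 down adjusted over the list alone, median 1.54, camera adjusted p = 0.00346, adjusted p = 0.747 with an estimated correlation). 189 of 247 ribosomal protein genes rose, 26 fell and 32 did not pass (189 up and 27 down adjusted over the list alone, median 0.90, camera adjusted p = 3.28e-19, adjusted p = 0.665 with an estimated correlation). 24 of 27 mitochondrion-encoded genes fell, 1 rose and 2 did not pass (median -4.13, camera adjusted p = 2.56e-13, adjusted p = 0.505 with an estimated correlation). In all 14168 genes changed, 6819 higher and 7349 lower, and 2884 and 2703 by more than 2-fold.

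In prmt5 the chaperones fell as well, the unfolded protein response and Sm genes fell from their higher heat level, and jasmonate, defence and flavonoid genes rose. HSP23.6 fell by 4.45. 17 of 19 small heat shock protein genes fell, 2 rose and 0 did not pass (median -2.8, camera adjusted p = 7.91e-08, adjusted p = 0.505 with an estimated correlation). HSP90.1 fell by 4.48. 22 of 23 chaperone genes fell, 1 rose and 0 did not pass (median -2.24, camera adjusted p = 3.92e-11, adjusted p = 0.505 with an estimated correlation). CNX1 fell by 3.06. 20 of 24 unfolded protein response genes fell, 3 rose and 1 did not pass (median -1.35, camera adjusted p = 3.27e-08, adjusted p = 0.505 with an estimated correlation). SMD3A fell by 2.49 and GRP8, a paralog of GRP7, rose by 2.19 ± 0.11. 19 of 27 genes of their list fell, 5 rose and 3 did not pass (median -1.41, camera adjusted p = 6.81e-06, adjusted p = 0.653 with an estimated correlation). The defence factor WRKY60 (AT2G25000) rose by 6.79 ± 0.20 (adjusted p = 3.4e-13). JAZ8 (AT1G30135), a jasmonate repressor, and MYC2 (AT1G32640), the pathway's central factor, rose by 4.12 ± 0.38 and 3.18 ± 0.25. 24 of 30 jasmonate genes rose, 2 fell and 4 did not pass (median 1.53, camera adjusted p = 0.00101, adjusted p = 0.653 with an estimated correlation). PAD3 rose by 5.91 ± 0.38. 17 of 22 salicylic acid and defence genes rose, 1 fell and 4 did not pass (median 1.5, camera adjusted p = 0.00481, adjusted p = 0.707 with an estimated correlation). LDOX rose by 4.56 ± 0.36. 18 of 20 flavonoid genes rose, 0 fell and 2 did not pass (median 2.08, camera adjusted p = 0.000495, adjusted p = 0.707 with an estimated correlation). 101 of 247 ribosomal protein genes fell, 73 rose and 73 did not pass (median -0.065, MR -0.36 with 46 up and 147 down, Q -0.014, camera adjusted p = 0.0102, adjusted p = 0.909 with an estimated correlation). 22 of 27 mitochondrion-encoded genes fell, 0 rose and 5 did not pass (0 up and 24 down adjusted over the list alone, median -2.37, camera adjusted p = 8.77e-11, adjusted p = 0.505 with an estimated correlation). In all 15806 genes changed, 9532 higher and 6274 lower, and 5451 and 2680 by more than 2-fold. Under median-ratio scaling, which moved the median of all genes from 0.21 to -0.027, the split was 7847 and 8308.

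At recovery prmt5 stood below WT in ribosomal protein, ribosome biogenesis, photosynthesis, flavonoid and cell cycle genes. It stood above WT in residual heat shock, autophagy, senescence, jasmonate, drought and sugar starvation genes, and in morning genes of the clock. 219 of 247 ribosomal protein genes fell, 14 rose and 14 did not pass (14 up and 220 down adjusted over the list alone, median -0.98, camera adjusted p = 8.46e-32, adjusted p = 0.505 with an estimated correlation), among them the stalk protein RPP0A (AT2G40010) at -2.47. Ribosomal protein genes took 13.33% ± 0.66 of TPM in WT at recovery and 6.99% ± 0.29 in prmt5, against 9.69% ± 0.3 and 10.05% ± 1.18 at 22 °C (SD, n = 3). FIB2 and the nucleolar protein NOP58 (AT3G05060) were at -1.92 and -1.23. 18 of 19 ribosome biogenesis genes fell, 0 rose and 1 did not pass (median -0.99, camera adjusted p = 6.79e-08, adjusted p = 0.7 with an estimated correlation). 8 of 9 methyltransferase genes fell, 0 rose and 1 did not pass (median -0.54, camera adjusted p = 0.00325, adjusted p = 0.722 with an estimated correlation), among them PRMT5 at -3.09 ± 0.17 and PRMT1A (AT2G19670) at -1.19 ± 0.14. The list was never tested without PRMT5, the disrupted gene. CA1 stood at 7.87 ± 2.11 TPM against 231 ± 87.7 in WT, and RBCS1B was at -4.36. 50 of 55 photosynthesis genes fell, 0 rose and 5 did not pass (median -1.71, camera adjusted p = 6.45e-10, adjusted p = 0.747 with an estimated correlation). The flavonoid hydroxylase TT7 (AT5G07990) was at -2.85. 17 of 20 flavonoid genes fell, 1 rose and 2 did not pass (median -1.43, camera adjusted p = 3.16e-05, adjusted p = 0.69 with an estimated correlation). CDC20.2 (AT4G33260) was at -2.08. 20 of 34 cell cycle genes fell, 2 rose and 12 did not pass (median -0.58, camera adjusted p = 0.000785, adjusted p = 0.747 with an estimated correlation).

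Among the higher genes, FOX2 (AT1G26390), an oxidase of defence metabolism, stood at 304 ± 135 TPM against 3.61 ± 2.79 in WT, and the glutathione transferase GSTU3 (AT2G29470) was higher by 5.9 ± 0.32 (adjusted p = 3.8e-09). HSP21 was higher by 2.14 ± 0.23. 14 of 19 small heat shock protein genes rose, 1 fell and 4 did not pass (median 0.96, camera adjusted p = 0.000148, adjusted p = 0.653 with an estimated correlation). GOLS1 was higher by 2.73 ± 0.18. 13 of 18 co-chaperone genes rose, 0 fell and 5 did not pass (median 0.68, camera adjusted p = 3.87e-05, adjusted p = 0.653 with an estimated correlation). HSFB1 (AT4G36990) was higher by 1.87 ± 0.28. 9 of 18 heat shock factors rose, 2 fell and 7 did not pass (10 up and 2 down adjusted over the list alone, median 0.49, camera adjusted p = 0.0373, adjusted p = 0.747 with an estimated correlation), a call that ended without WT recovery library 1 (median 0.40). ATG8H was higher by 1.76 ± 0.21. 18 of 21 autophagy genes rose, 0 fell and 3 did not pass (median 0.67, camera adjusted p = 2.82e-07, adjusted p = 0.505 with an estimated correlation). The longevity factor JUB1 (AT2G43000) and the senescence regulator ORE1 (AT5G39610) were higher by 2.97 ± 0.31 and 2.12 ± 0.32. 14 of 20 senescence genes rose, 2 fell and 4 did not pass (15 up and 2 down adjusted over the list alone, median 0.92, camera adjusted p = 0.000194, adjusted p = 0.505 with an estimated correlation). The dehydrin LTI30 (AT3G50970) was higher by 2.94 ± 0.37. 16 of 28 genes of abscisic acid, dehydration and cold rose, 3 fell and 9 did not pass (median 0.82, camera adjusted p = 0.0021, adjusted p = 0.707 with an estimated correlation). JAZ8 was higher by 3.5 ± 0.38. 13 of 30 jasmonate genes rose, 4 fell and 13 did not pass (median 0.31, camera adjusted p = 0.00931, adjusted p = 0.707 with an estimated correlation). The starvation-induced glucosidase DIN2 (AT3G60140) was higher by 4.3 ± 0.49. 8 of 14 sugar starvation genes rose, 1 fell and 5 did not pass (9 up and 1 down adjusted over the list alone, median 0.68, camera adjusted p = 0.00897, adjusted p = 0.653 with an estimated correlation). The morning genes LHY and CCA1 (AT2G46830) stood at 73.7 ± 9.11 and 50.5 ± 5.44 TPM against 5.03 ± 0.165 and 4.69 ± 0.845 in WT. 13 of 25 clock genes rose, 8 fell and 4 did not pass (median 0.23, Q 0.40, camera adjusted p = 0.0455, adjusted p = 0.707 with an estimated correlation), a list call that ended under several alternatives, median-ratio scaling among them (median 0.32). 18 of 27 mitochondrion-encoded genes rose, 1 fell and 8 did not pass (median 0.95, camera adjusted p = 1.02e-05, adjusted p = 0.505 with an estimated correlation), with a median of 1.02 without prmt5 library 3, which stood apart. In all 13034 genes differed, 6059 higher and 6975 lower in prmt5, and 1798 and 2542 by more than 2-fold.

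**Figure D3:**
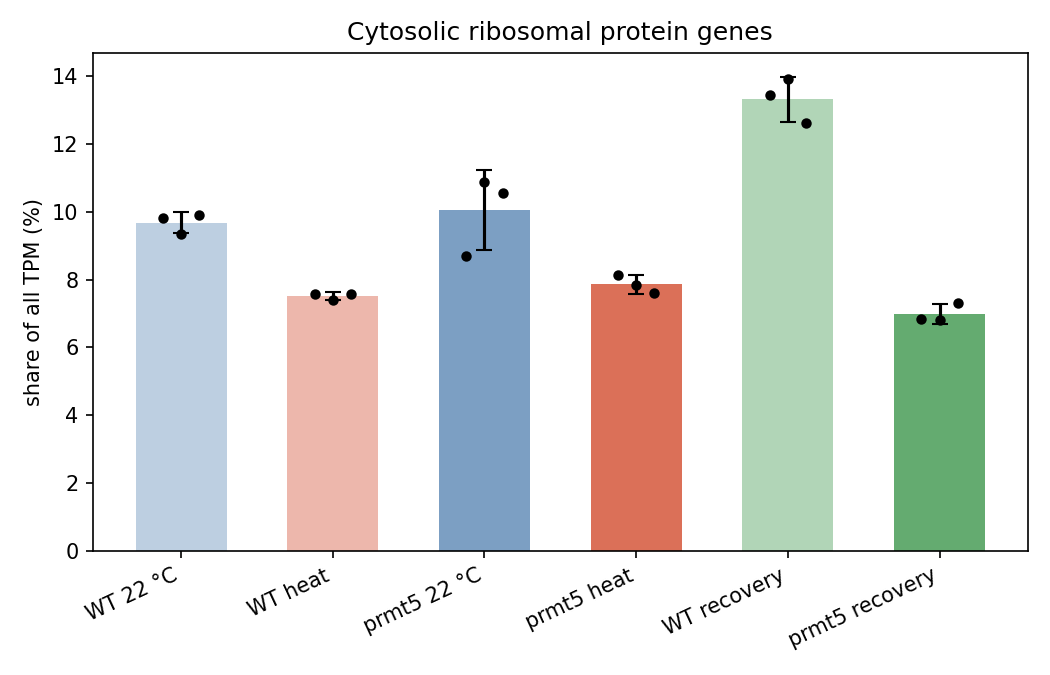
Share of each library's TPM, in percent, taken by ribosomal protein genes, by genotype and condition; points are libraries, and bars with error bars are the mean and SD of 3 libraries. The mean is 13.33% in WT at recovery and 6.99% in prmt5.

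**Figure D4:**
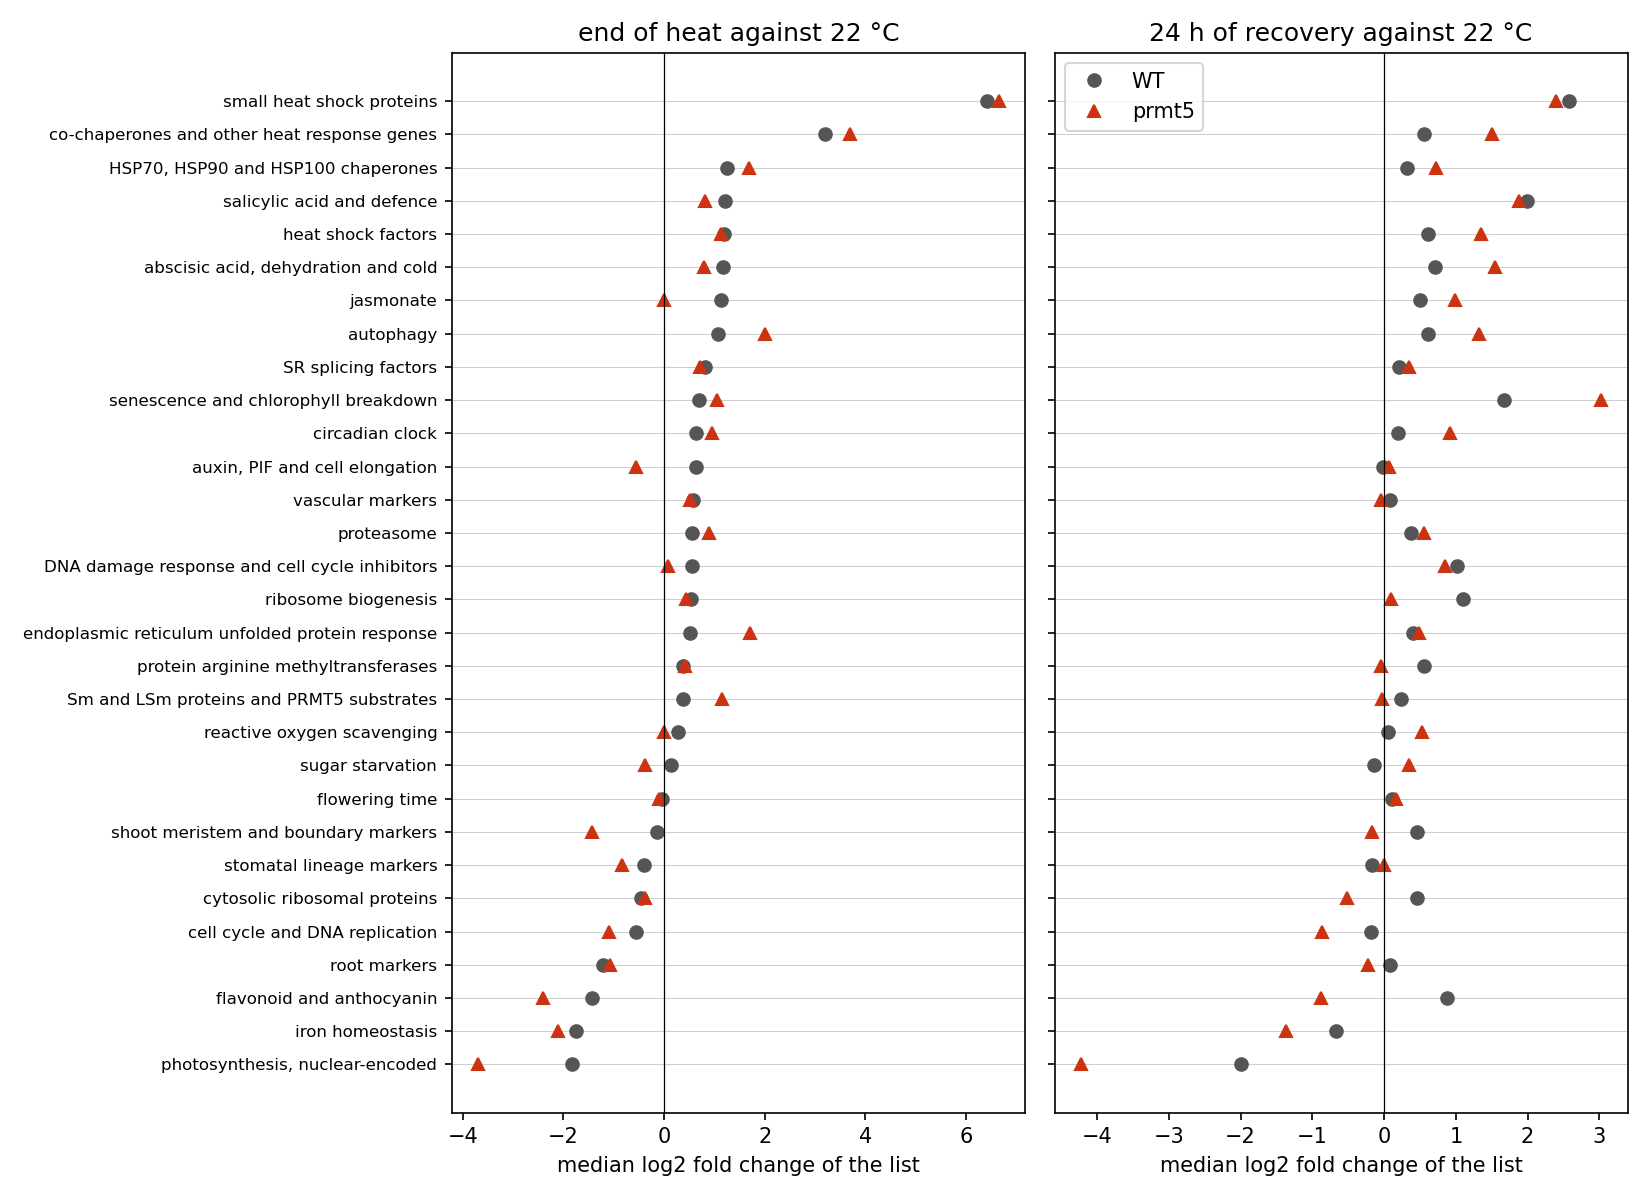
Median log2 change of gene lists at heat and at recovery against unheated plants, by genotype. Photosynthesis genes are lower at heat in both genotypes, with medians of -1.82 in WT and -3.70 in prmt5.

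The difference between the genotypes' responses was tested itself. The heat response differed for 11201 genes, 3924 with a higher and 7277 with a lower change in prmt5, and under median-ratio scaling, which moved the median of all genes from -0.19 to 0.019, for 5989 and 5586. 18 of 24 unfolded protein response genes rose, 2 fell and 4 did not pass by this test (21 up and 2 down adjusted over the list alone, median 0.87, camera adjusted p = 8.63e-11, adjusted p = 0.505 with an estimated correlation). 47 of 55 photosynthesis genes fell, 0 rose and 8 did not pass (median -2.09, camera adjusted p = 1.76e-07, adjusted p = 0.747 with an estimated correlation). The recovery response against 22 °C differed for 10084 genes, 5699 higher and 4385 lower, and there 218 of 247 ribosomal protein genes fell, 11 rose and 18 did not pass (median -1.0, camera adjusted p = 3.13e-43, adjusted p = 0.505 with an estimated correlation). The change from heat to recovery differed for 10726 genes, 7666 higher and 3060 lower, or 5183 and 5140 under median-ratio scaling, which moved the median of all genes from 0.28 to 0.016. There 22 of 30 jasmonate genes rose, 0 fell and 8 did not pass (23 up and 0 down adjusted over the list alone, median 1.69, camera adjusted p = 8.02e-06, adjusted p = 0.505 with an estimated correlation). PRMT5 itself did not pass in any of the 3 tests, with log2 differences of 0.020 ± 0.23 (adjusted p = 0.95), -0.43 ± 0.23 (0.15) and -0.45 ± 0.23 (0.12).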

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

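The tests of poly(A) selection, nuclear copies of mitochondrial DNA, scaling, a single library, time of day and splits without the shared genotype difference were chosen after the results were seen. Interaction results were picked out because the response of prmt5 differed from that of WT by the test of limma, and their log2 differences are the prmt5 response minus the WT response.

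The heat response differed for 11201 genes. By camera, median differences in list members were 0.87 for the unfolded protein response, 0.92 for autophagy, 0.54 (Q 0.361) for HSP70, HSP90 and HSP100 chaperones, 0.43 (MR 0.686) for co-chaperones, 0.42 (MR 0.663) for Sm and LSm genes and 0.40 (MR 0.642, Q 0.253) for the proteasome. They were -2.09 for photosynthesis, -1.20 for the cell cycle, -1.17 for flavonoids and -1.09 for jasmonate. Single genes with a higher change in prmt5 were GAUT14 (4.42), U2.5 (4.04), ERF114 (3.99), RABA1e (AT4G18430) (3.94) and CYP89A7 (AT1G64930) (3.79), with GAUT14 and U2.5 listed at 0 in WT at heat. Those with a lower change were VSP2 (-5.42), IPMI1 (-5.21), LOX2 (-4.90), the glucosidase BGLU18 (AT1G52400) (-4.87) and AT14A (AT3G28300) (-4.73). Adjusted p for these lists ran from 8.63e-11 to 0.00794, and from 0.505 to 0.747 with an estimated correlation.

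The recovery response against 22 °C differed for 10084 genes. List medians were 1.06 for small heat shock proteins, 0.79 for co-chaperones, 0.78 for mitochondrion-encoded genes, 0.72 for senescence and 0.68 for autophagy. They were -2.23 for photosynthesis, -1.14 for flavonoids, -1.0 for ribosomal proteins, -0.94 for ribosome biogenesis and -0.85 for the cell cycle. Adjusted p ran from 3.13e-43 to 0.00264, and from 0.505 to 0.739 with an estimated correlation. Genes with a higher change were FOX2 (6.15), GSTU3 (5.90, listed at 0 at 22 °C), U2.14 (5.32, listed at 0 in WT at recovery), LHY (5.28) and CYP71B22 (AT3G26200) (5.18). Those with a lower change were RPS27AA (-5.34, above 0 only in WT at recovery), MLP28 (AT1G70830) (-4.61), COR15B (-4.46), LURP1 (-4.45) and RBCS1B (-4.34).

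The change from heat to recovery differed for 10726 genes. List medians were 1.70 for mitochondrion-encoded genes, 1.69 for jasmonate and 1.62 for small heat shock proteins, and -0.97 for ribosomal proteins, -0.95 for the unfolded protein response, -0.77 for ribosome biogenesis and -0.58 (MR -0.885) for Sm and LSm genes. Adjusted p ran from 2.77e-52 to 0.00104, and from 0.505 to 0.7 with an estimated correlation.

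Other splits of the libraries were tried for each count. For the 9 comparisons of 2 groups there are only 10 splits, too few for a share under 0.05, with 1 as large each time, the real one. Real and highest other counts were 16481 and 1 (WT heat), 17783 and 1 (prmt5 heat), 14646 and 1 (WT recovery against 22 °C), 17033 and 0 (prmt5 recovery against 22 °C), 14168 and 1 (WT recovery against heat), 15806 and 2 (prmt5 recovery against heat), 3256 and 211 (genotypes at 22 °C), 14885 and 3 (at heat) and 13034 and 2 (at recovery). For the interactions in the order above 7, 1 and 1 of 100 splits gave as many genes, with highest other counts of 13126, 10021 and 10386. These came from splits that kept the genotypes of 1 condition whole and so carried the real genotype difference, and they say nothing on chance. With the shared genotype difference taken out of the log values, only the real split of 100 gave as many. Counts were 11200, 10080 and 10731 against 6923, 5113 and 5147. Others mix real differences too, so chance was not tested. The same holds for the shared heat genes (1 of 100, 13622 against 847). For the lists called chance was not excluded, as 6 of 100 reassignments gave as many as 174, up to 178. Reassigned groups still hold libraries of different conditions.

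Mitochondrion-encoded transcripts rose after heat in both genotypes, with median log2 changes of 7.22 and 6.86. Carry-over of RNA without poly(A) tails would raise plastid-encoded genes too, and their higher median was 0.0177, with -0.88 in prmt5, while their share in WT went from 0.078% to 0.197% of TPM, which argues against it as the whole cause. Nuclear ribosomal RNA, also without such tails, rose from 0.39% to 1.64% of TPM in WT, so a smaller part of this kind stays open. Reads of the nuclear copy of mitochondrial DNA cannot be told apart from those of the organelle: TPM in that region was 0.82 ± 0.07 of the mitochondrial TPM in WT and 0.40 ± 0.04 in prmt5 (SD, n = 3). Condition, the biological explanation, stays open as a hypothesis.

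Ribosomal protein genes stood lower in prmt5 at recovery. Scaling of TPM is argued against, since the median of -0.99 stayed at -0.90 or lower under median-ratio scaling, quantile normalization and nuclear genes only. Gene length is argued against by 10000 lists matched on length and expression, whose medians centred on -0.0991 and ran from -0.33 to 0.0952. A single library is argued against by the median of -1.02 without prmt5 recovery library 3. An effect of genotype on the return of ribosomal genes after heat may explain the difference, as a hypothesis found on these data.

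Morning clock genes stood higher in prmt5 at recovery, 8 of 8 with a median of 1.93, while 5 of 8 evening genes were lower and 1 was higher, with a median of -0.44. A different hour of harvest would move both sets in this way, and so could a shifted clock in the mutant, so these cannot be told apart without the harvest time. The medians for morning and evening genes were -0.64 and 0.41 at 22 °C and -0.64 and -0.13 at heat.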

How the results depend on the processing

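The 2 added alternatives were chosen after the data were seen, and the others were planned. Of all counts and main values under the alternatives, 451 stayed within 1.5 times the value reported and 7 did not. Those 7 belong to the genotypes at 22 °C and to the list tests. At 22 °C, 3256 genes became 1498 with only the groups compared in the fit and 13082 with array weights, whose fit stopped before convergence and gave prmt5 library 2 a weight of 25.29. Leaving out a library there gave 1679 to 4038 genes. For lists, 174 calls became 0 with camera's estimated correlation and 267 with fry, and the cause was not tested.

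Directions reversed in 7 cases with a call, judged for lists by the test. The medians of 12 lists changed sign under median-ratio or quantile scaling. Under median-ratio scaling the proteasome in WT recovery against 22 °C had a median of -0.00422, by the removal of the shift of all genes. Under quantile normalization ribosomal proteins in prmt5 recovery against heat had -0.014 with a test in the other direction, and PRMT5 in prmt5 recovery against 22 °C had -0.26, and the cause was not tested. Under fry the test direction turned for reactive oxygen (median 0.273), elongation (0.627) and vascular genes (0.567) in WT heat and for small heat shock proteins between the genotypes at heat (0.0528), since fry follows the members' own direction and camera the contrast with other genes.

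For single genes named, 20410 values kept direction and side of the threshold, 102 lost and 7 gained a call, and 8 moved. For lists 4814 kept both, 210 lost and 25 gained a call, and 29 moved. Among these are 2 lists with too few members for camera, judged by their median alone. Without the filter camera could test them, and the medians became 0.095 for seed maturation (1.78 with 2 members, adjusted p = 0.577) and 0.823 for floral markers (2.29 with 2 members, adjusted p = 0.171). Genes that an alternative removed have no value there, nor has seed maturation at a minimum mean TPM of 5. Leaving out a library gave 15594 to 16784 genes for WT heat, 17135 to 17908 for prmt5 heat, 13488 to 15110 and 16236 to 17134 for recovery against 22 °C in WT and prmt5, 13043 to 14579 and 14992 to 16208 for recovery against heat, 13660 to 15310 for the genotypes at heat and 11546 to 13571 at recovery. It gave 9987 to 11764, 8893 to 10302 and 9577 to 11416 for the interactions, 170 to 179 called list tests, 12945 to 13663 shared heat genes and a PRMT5 difference of -33.11 to -32.44 TPM.

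Equal replicate numbers do not pair the libraries: of 27 pairs of libraries with the same number 5 correlated above 0.1, within -0.195 to 0.189, and the same number was the best match in 9. With the replicate number as a block the counts were 16374, 17671, 14495, 16914, 13968 and 15666 for the responses in the order above, 2902, 14699 and 12790 for the genotypes and 10909, 9786 and 10474 for the interactions. Depth limits cannot be given for TPM.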

Other observations

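Annotated gene terms add groups that the lists do not hold. They were all chosen after the results were seen, out of 631 terms in 12 comparisons, of which camera called 925 of 7572 tests at its preset correlation and 0 with an estimated correlation (adjusted p = 0.999). Genes of DNA integration, of which 93 of 108 are pseudogenes described as transposable elements and 7 lie in the copy of mitochondrial DNA, rose at heat in WT (99 rose, 4 fell, median 2.67, adjusted p = 6.68e-13) and in prmt5 (96 rose, 6 fell, median 2.06). From heat to recovery 84 of them fell in WT and 74 in prmt5, and at recovery 83 and 78 were above 22 °C. Low-oxygen response genes stood higher in prmt5 at recovery (149 higher, 21 lower of 245, median 0.66, adjusted p = 1.38e-08), among them the oxidase FOX1 (4.02), the carboxylesterase CXE6 (3.68) and the calmodulin-like CML44 (3.5). Genes of toxin catabolism leaned the same way (24 higher, 8 lower of 44, median 0.815, adjusted p = 0.0135), with the glutathione transferases GSTU10 (3.14) and GSTF3 (2.85) higher and GSTU20 (-3.62) lower.

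Glucosinolate genes differed in the heat response (2 with a higher and 23 with a lower change in prmt5 of 30, median -1.76, adjusted p = 0.00015), with CYP79F1 (-4.25), CYP83A1 (-3.76) and MAM1 (-3.69), enzymes of the aliphatic pathway, among them. Motor proteins of microtubule-based movement stood lower in prmt5 at heat (54 of 62, median -1.03, adjusted p = 0.000134), with the kinesins FRA1 (-2.23) and POK2 (-2.11). At 22 °C 24 of 95 RNA modification genes stood higher in prmt5 and 2 lower (median 0.24, adjusted p = 6.91e-14), among them the organelle RNA editing gene PCMP-E14 (1.01).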
